A study of Homo sapiens with 15 samples.

How the data were processed

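RNA from stress granules isolated from HK-2 cells was measured in 15 libraries, 3 from each of 5 groups. The authors extracted RNA with Trizol, selected poly(A) RNA, made stranded (dUTP) libraries and sequenced paired reads of 150 bases. Per the labels they trimmed reads with cutadapt 1.9, checked them with FastQC, aligned them to hg38 with HISAT2 and assembled and quantified transcripts with StringTie 1.3.4d, and used DESeq2 and edgeR. How StringTie's coverage became counts, and with which strand option, is not stated.

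The count matrix deposited by the authors holds whole-number counts per Ensembl gene, not normalised, for 60612 genes. In every library genes at exactly 4 counts outnumber those at 3 and at 5, so 1 sequenced fragment may be more than 1 count. The FPKM values deposited by the authors are scaled to transcript length and library size, as StringTie gives them, and were not used for tests. A second table holds the same counts and the FPKM for the 41774 genes with at least 1 count. The 18838 genes it leaves out hold 2 counts in total. The 3 comparison tables deposited by the authors give a fold change as the ratio of group means, its log2, a p-value and an adjusted q-value. The test behind them is not stated. Their marks of significance coincide with a q-value under 0.05 and at least a 2-fold change.

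Symbols, classes and positions on hg38 came from the deposited annotation and from GENCODE release 29, in which 40417 genes (96.8%) had a transcript. Libraries were assigned to groups by their labels alone, and no library was left out. Total counts ran from 53594252 to 66864675, so a gene at 1 CPM has over 50 counts in each library. A floor for a gene at 0 in a group is 3 counts over the group's total. If 1 fragment is more than 1 count, this floor may lie under 1 fragment, and a fold against it is then not a lower bound.

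Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group (24739 genes kept) and a quasi-likelihood F test with 5 group means in 1 fit of the 15 libraries. P-values were adjusted by Benjamini and Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. edgeR's prior count of 0.125 enters log2 fold changes. The 7 contrasts were H2O2, heat shock and DMSO against media, FG4592 against DMSO, H2O2 against heat shock, and the FG4592 response minus the H2O2 or the heat shock response. No label says that a replicate number marks a shared culture or day, so the numbers were not treated as pairs. Correlations across genes between the deviations of libraries with the same replicate number ran from -0.129 to 0.0798.

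Lists of 602 genes in 26 groups, of which 600 were found (SLC22A6 and EMCN were not), were fixed before the data were examined, as were the comparisons, tests and most alternatives. They cover heat shock chaperones, NRF2 targets, p53 targets, HIF targets, other than glycolysis, glycolysis and glucose uptake, ATF4 and amino acid response, ER chaperones, immediate early genes, NF-kB and inflammatory mediators, BCL2 family and caspases, stress granule proteins, m6A writers, erasers and readers, tubular injury and epithelial markers, proximal tubule transport, fibroblast and matrix, endothelial markers, leukocyte markers, mitochondrially encoded mRNAs, nuclear-retained long noncoding RNAs, cytosolic ribosomal proteins, oxidative phosphorylation, nuclear, DNA replication, mitosis, replication-dependent histones, cholesterol synthesis, metallothioneins. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 26 lists, again with an estimated correlation, and with fry. The list named nuclear-retained also holds largely cytoplasmic RNAs such as NORAD. Some lists share genes, such as BBC3 in the p53 and BCL2 lists.

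Named genes were chosen by a rule fixed at the same time. For H2O2, heat shock and FG4592 against their controls these were the 5 largest rises and 5 largest falls among called genes with a known symbol, a mean of at least 5 CPM over the 2 groups and all 3 treated libraries on 1 side of all 3 controls. For each list described, the 2 called members with the largest change and a mean of at least 1 CPM were added, or the member with the highest mean where none was called. A fixed set of 16 genes was added whatever its result: YTHDF1, G3BP1, HSPA1A, HSPA1B, DNAJB1, HMOX1, CDKN1A, CA9, VEGFA, EGLN3, AHNAK, DYNC1H1, NORAD, TFRC, GAPDH and ACTB. For DMSO against media and H2O2 against heat shock the 3 largest rises and falls were named. Any other named gene is stated to be chosen after its values were seen.

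Alternatives changed 1 choice at a time, except that the replicate block was fitted with the compared groups alone and that the DESeq2 Wald test brought its own size factors and filter. They were DESeq2 size factors and upper-quartile factors in the same fit, the DESeq2 1.42.0 Wald test, limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, fits of the compared groups alone, that fit with a block for replicate number, and leaving out each library in turn. Length was also compared for genes of at least 10 CPM. Chosen after the data were seen were counts divided by 4, protein-coding genes alone, the DMSO libraries as controls for H2O2 and heat shock, and list medians under the other scalings. Groups were also reassigned at random, in all 10 splits of 6 libraries or 100 drawn splits of more. The correlation and covariance of fold changes that share controls were set beside 20 simulated data sets of unchanged groups with the same spread.

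The test was tested on simulated data with the depth of the 15 libraries, the spread of the fit of all groups and the media mean in each group. The changed genes counted here had at least 1 CPM in media. The test called 12 of 67 genes changed 1.5-fold (17.9%), 45 of 67 changed 2-fold (67.2%) and 59 of 66 changed 4-fold (89.4%). Of 129 calls, 3 were of unchanged genes, and with nothing changed it made 0 calls. The real comparison of H2O2 and media gave 12038 calls. With few changed genes the adjusted threshold is stricter, so these shares do not give the sensitivity of the real tests. Tables were joined and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.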

Results

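RNA was sequenced from stress granules isolated from HK-2 cells, an immortalised line of human proximal tubule cells. Stress granules are bodies of untranslated mRNA and RNA-binding protein that form in the cytoplasm when translation stalls. The 15 libraries formed 5 groups of 3. They came from untreated cells in medium (media), cells given 4 h of hydrogen peroxide (H2O2), cells kept at 45 °C for 1 h (heat shock), and cells given 12 h of DMSO or of FG4592. FG4592 (roxadustat) inhibits the prolyl hydroxylases that mark the transcription factor HIF for degradation, and DMSO is its vehicle. The labels do not say whether the 6 control libraries came from the same fractionation, and total RNA beside the fraction was not analysed here. A fold change is therefore a difference between groups in the RNA as sequenced, not an enrichment in granules over the cell. Nor do the labels say that replicates were separate cultures, so the p-values may measure technical spread alone.

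Total counts per library ran from 53594252 to 66864675. The authors' counts place genes at exactly 4 counts more often than at 3 or 5 in all 15 libraries (medians of 1070, 796 and 437 genes), so 1 sequenced fragment may be more than 1 count. Genes with at least 1 count numbered 32633 ± 337 (SD, n = 3) in the H2O2 libraries and 24794 ± 681 (SD, n = 3) in media. On the first principal component the H2O2 libraries lay apart from all others, and replicates of each group lay together.

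**Figure D1:**
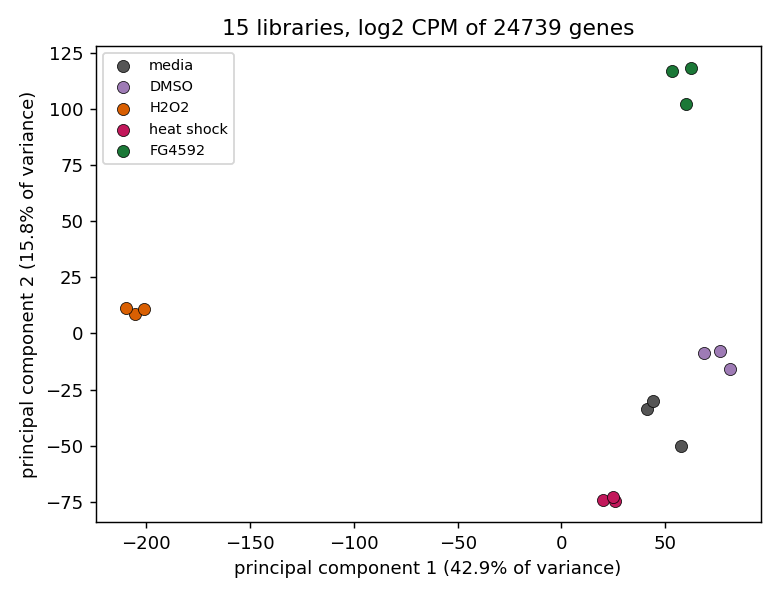
Principal components of the 15 libraries from log2 CPM, with component 1 (42.9% of the variance) on the x axis and component 2 (15.8%) on the y axis, each point being a library coloured by group. The 3 H2O2 libraries lie between -210 and -201 on component 1 and the other 12 between 19.9 and 81.4.

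The first comparison asks how RNA of the stress granule fraction differs after oxidative stress from that of untreated cells. HMOX1, the heme oxygenase of the antioxidant response, was 9.13-fold higher after H2O2, and the stress transcription factor genes ATF3 and FOS were 35.5-fold and 72.6-fold higher. DNA replication genes fell as a list, as did mitosis genes in a call lost with an estimated correlation (adjusted p = 0.059). GAPDH and PKM of glycolysis and ACTB of the cytoskeleton fell too. Of 5492 long noncoding RNAs past a filter that H2O2 reads alone can meet, 2067 rose, 150 fell and 3275 were not called. YTHDF1, the reader of m6A (methylated adenosine) in mRNA that the series is about, rose 1.25-fold.

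Of 24739 genes tested with edgeR, 12038 differed between H2O2 and media at an adjusted p under 0.05, of which 6483 rose and 5555 fell. At least 2-fold rises numbered 4881 and falls 1303. The split depended on scaling: upper-quartile factors moved the median of all genes up by 0.19 log2 and gave 7819 rises and 3928 falls (66.6% up against 53.9%). Changes of that size or less therefore have a direction that rests on the scaling. With the DMSO libraries as controls, an alternative chosen after the data were seen, 8563 of the 12038 genes (71.1%) were called in the same direction and 481 in the opposite one.

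HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35390293 on hg38) rose from 20.5 ± 1.68 CPM in media to 187 ± 17.4 CPM in H2O2 (SD, n = 3; log2 fold change 3.19, SE 0.12, adjusted p = 1.8e-10). YTHDF1 (ENSG00000149658, chromosome 20, 63195429 to 63216139) measured 87.9 ± 8.05 CPM and 109.8 ± 3.62 CPM (SD, n = 3; log2 fold change 0.32, SE 0.09, adjusted p = 0.0089), and against DMSO its log2 fold change was 0.06 and not called. G3BP1, a core protein of stress granules (ENSG00000145907, chromosome 5, 151771045 to 151804225), fell 2.07-fold (log2 fold change -1.05, SE 0.09, adjusted p = 8.06e-07). CDKN1A, an inhibitor of the cell cycle, rose 5.31-fold (adjusted p = 2.18e-09). GAPDH and ACTB, often used as reference genes, fell 2.05-fold and 2.69-fold. Both fell under all 3 scalings tried, and against DMSO their log2 fold changes were -1.65 and -0.67.

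The 5 largest rises among known genes with all 3 treated above all 3 control libraries, which chance gives in 5% of genes, were BIVM-ERCC5, OVOL1, FAM71A, PTGER3 and ENDOU. The media libraries had no count of OVOL1, an epithelial transcription repressor, or of FAM71A. Against a floor of 3 counts over the group, these genes were 736-fold and 596-fold higher. BIVM-ERCC5, a readthrough transcript, also had no media count and was 2440-fold higher against that floor, an uncertain value. The genes it spans, BIVM and ERCC5 (chosen after their values were seen), fell 2.14-fold and 4.89-fold, and BIVM-ERCC5 itself was not called against DMSO. FAM71A lies just downstream of ATF3 on the same strand. PTGER3, a prostaglandin receptor gene, rose from 0.0218 ± 0.0377 CPM to 28.3 ± 4.18 CPM, and ENDOU, an endoribonuclease gene, from 0.0381 ± 0.066 CPM to 37.2 ± 3.47 CPM (SD, n = 3). The 5 largest falls were CD68 (9.0-fold, in a locus overlapped by another gene model), the mitochondrial tRNA gene MT-TY (6.47-fold), the transcription co-activator subunit TADA1 (6.42-fold), CDC42EP2 of actin regulation (6.15-fold) and MT-ND6 of respiratory complex I (5.69-fold). Floors cover counting error only.

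Of 26 gene lists fixed before the data were examined, 12 were called by camera with a preset correlation of 0.01, and 2 of them, the immediate early and the DNA replication genes, also with an estimated correlation. At the preset correlation, 6 of 10 splits of these libraries, the real one included, called 12 or more lists (highest other 13). The number of lists called thus does not exceed that of other splits. Each other split mixes both groups unevenly and keeps part of their difference, so the splits cannot show whether 12 lists exceed chance. Among 29 immediate early genes, which respond within minutes to a stimulus, 23 rose and 2 fell (23 and 3 adjusted over the list alone), with a median log2 fold change of 1.71 (adjusted p = 5.17e-21, and adjusted p = 0.0245 with an estimated correlation). EGR3 rose 254-fold and FOS 72.6-fold. In DNA replication 0 rose and 22 fell (0 and 23 adjusted over the list alone) of 26 (adjusted p = 1.64e-10, and adjusted p = 0.022 with an estimated correlation), with MCM5 of the replicative helicase down 2.35-fold and RRM2 of ribonucleotide reductase down 2.34-fold. The mitosis genes went the same way: 0 rose and 23 fell (0 and 23 adjusted over the list alone) of 24 (adjusted p = 1.13e-16, and adjusted p = 0.059 with an estimated correlation), among them the kinase PLK1 (2.97-fold) and the cyclin CCNA2 (2.77-fold).

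Glycolysis and glucose uptake was called down after H2O2, since 5 rose and 15 fell (5 and 15 adjusted over the list alone) of 21 (adjusted p = 1.39e-06, and adjusted p = 0.0718 with an estimated correlation). PKM, a pyruvate kinase gene, fell 2.63-fold, and ALDOC, an aldolase gene, rose 4.77-fold, although not against DMSO. Ribosomal protein genes rose: 57 rose and 0 fell (59 and 1 adjusted over the list alone) of 78 (adjusted p = 1.35e-06, and adjusted p = 0.613 with an estimated correlation), RPS12 by 1.66 and RPS29 by 1.46 log2. Among 13 mitochondrially encoded mRNAs 0 rose and 8 fell (0 and 10 adjusted over the list alone), MT-ND6 and MT-ND5 most (5.69-fold and 4.18-fold, adjusted p = 0.00451, and adjusted p = 0.613 with an estimated correlation). MT-ND5 was not called without media replicate 2 (-1.25) and NDUFA1 was not called without media replicate 2 (0.90). Nuclear genes of oxidative phosphorylation split, as 6 rose and 13 fell (6 and 14 adjusted over the list alone) of 34 (adjusted p = 0.00419, and adjusted p = 0.613 with an estimated correlation). SDHA fell 2.32-fold and NDUFA1 rose 2.05-fold, and the list's median, -0.17, turned to 0.02 under upper-quartile factors. The list was not called with a filter of 1 CPM (adjusted p = 0.108) or a replicate block (adjusted p = 0.0552). Cholesterol synthesis genes mostly fell, 3 rose and 14 fell (3 and 14 adjusted over the list alone) of 22 (adjusted p = 0.00379, and adjusted p = 0.276 with an estimated correlation), NSDHL 2.29-fold, while STARD4 of sterol transport rose 2.05-fold; with a filter of 1 CPM the list was not called (adjusted p = 0.0771).

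Of 30 genes for stress granule proteins, 3 rose and 16 fell (3 and 17 adjusted over the list alone) (adjusted p = 0.000936, and adjusted p = 0.211 with an estimated correlation), with ATXN2 and UBAP2L, both needed for granule assembly, down 2.33-fold and 2.2-fold. With a filter of 1 CPM this list was not called (adjusted p = 0.0518). The m6A writers, erasers and readers were not called (4 rose and 11 fell of 20, 4 and 11 adjusted over the list alone, adjusted p = 0.0991), but were called without H2O2 replicate 1 at 0.0454, H2O2 replicate 2 at 0.0316, media replicate 1 at 0.0389 or media replicate 3 at 0.0244. Of them the writer component RBM15B rose 2.36-fold and the demethylase FTO fell 2.17-fold. Tubular injury and epithelial markers were called down: 1 rose and 16 fell (1 and 16 adjusted over the list alone) of 20 (adjusted p = 1.34e-05, and adjusted p = 0.198 with an estimated correlation). LCN2, an injury marker, fell 4.59-fold, and the developmental transcription factor SOX9 rose 5.08-fold. Fibroblast and matrix genes were called down, 2 rose and 8 fell (2 and 8 adjusted over the list alone) of 14 (adjusted p = 0.0164, and adjusted p = 0.276 with an estimated correlation), with a median of -0.58 but a mean of 0.07. TAGLN fell 2.13-fold and POSTN rose 2.04-fold, neither called against DMSO. POSTN was not called without H2O2 replicate 2 (0.99), H2O2 replicate 3 (0.92), media replicate 1 (0.99) or media replicate 2 (0.75). In a list of known long noncoding RNAs, named nuclear-retained although NORAD and other members are largely cytoplasmic, 8 rose and 1 fell (8 and 1 adjusted over the list alone) of 12 (adjusted p = 3.16e-05, and adjusted p = 0.113 with an estimated correlation), NORAD 4.5-fold and SNHG5 3.81-fold.

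Of the 14 lists not called after H2O2, the heat shock chaperones split (11 rose and 9 fell of 27, 11 and 10 adjusted over the list alone, adjusted p = 0.38), with HSPA1L up 3.88-fold, HSPB8 up 2.44-fold and DNAJB1 up 2.37-fold, the last not called against DMSO. HSPA6, which that list does not hold (chosen after its values were seen), rose 104-fold (adjusted p = 4.88e-09). HSPA1A was not called (0.13 log2, adjusted p = 0.361, from 0.0292 to 0.806 over 12 alternatives) and HSPA1B rose 1.28-fold. HSPA1B was not called without H2O2 replicate 1 (0.27). These are near-identical genes of uncertain separate values, and both were lower than in DMSO (-1.08 and -1.13 log2). Of the NRF2 targets (5 rose and 12 fell of 25, 5 and 12 adjusted over the list alone, adjusted p = 0.477) the transporter ABCC2 rose 21.8-fold, and of the p53 targets (9 rose and 6 fell of 25, 10 and 6 adjusted over the list alone, adjusted p = 0.757) the kinase PLK2 fell 2.84-fold, not called against DMSO. HIF targets split as well (7 rose and 12 fell of 28, 8 and 13 adjusted over the list alone, adjusted p = 0.477, called without media replicate 1 at 0.0405), with ANKRD37 and EGLN3 up 8.08-fold and 4.05-fold, CA9 not called (-0.32 log2), and VEGFA not called (0.35 log2, adjusted p = 0.0562, from 0.00633 to 0.182 over 12 alternatives). Against DMSO, EGLN3 was not called and VEGFA was lower (-0.96 log2). CA9 was called without media replicate 1 (-0.49). In the ATF4 response (5 rose and 11 fell of 24, 5 and 11 adjusted over the list alone, adjusted p = 0.935) DDIT3, a proapoptotic factor, rose 14.1-fold. ER chaperones (8 rose and 5 fell of 18, 9 and 5 adjusted over the list alone, adjusted p = 0.193) included rises of HSPA5 (2.56-fold) and HERPUD1 (2.3-fold). In the inflammatory list (5 rose and 6 fell of 21, 5 and 6 adjusted over the list alone, adjusted p = 0.757) TNF rose 2.72-fold and the inhibitor TNFAIP3 2.4-fold. Of the BCL2 family (7 rose and 7 fell of 21, 7 and 7 adjusted over the list alone, adjusted p = 0.637) BCL2L11 rose 3.68-fold, not called against DMSO, and MCL1 2.59-fold.

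Proximal tubule transport genes were not called (2 rose and 1 fell of 14, 2 and 1 adjusted over the list alone, adjusted p = 0.86), with GGT1 down 2.25-fold. Markers of other cell types were not called either: endothelial genes (4 rose and 1 fell of 11, 4 and 1 adjusted over the list alone, adjusted p = 0.547, EGFL7 down 1.58-fold but not called against DMSO) and leukocyte genes (5 rose and 2 fell of 9, 5 and 2 adjusted over the list alone, adjusted p = 0.457, ITGAM up 13.3-fold and CD68 down). No histone gene of 14 was called by edgeR (adjusted p = 0.935; 1 at an unadjusted p under 0.05, and 0 called by DESeq2 or limma-voom), H2BC12 being -0.34 log2 (called without H2O2 replicate 1, -0.44). Metallothioneins were not called (4 rose and 0 fell of 8, 5 and 0 adjusted over the list alone, adjusted p = 0.2), with MT1M up 2.56-fold and MT1G up 2.12-fold, while against DMSO MT1M was not called and MT1G was lower. The median and the mean differed in sign for NRF2, HIF and ATF4 targets, whose medians were negative. For ATF4 targets the test had the sign of the mean, and for proximal tubule genes it was down while median and mean were above 0. Of the other genes fixed in advance, DYNC1H1, a long motor protein mRNA, fell 2.4-fold, AHNAK fell 1.47-fold and TFRC of iron uptake was not called (0.33 log2). AHNAK was 0.98 log2 higher than in DMSO. With DMSO as the control, cholesterol synthesis, fibroblast, oxidative phosphorylation and tubular injury genes were not called as lists, and 3 others were: HIF targets and chaperones down, ATF4 targets up.

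**Figure D2:**
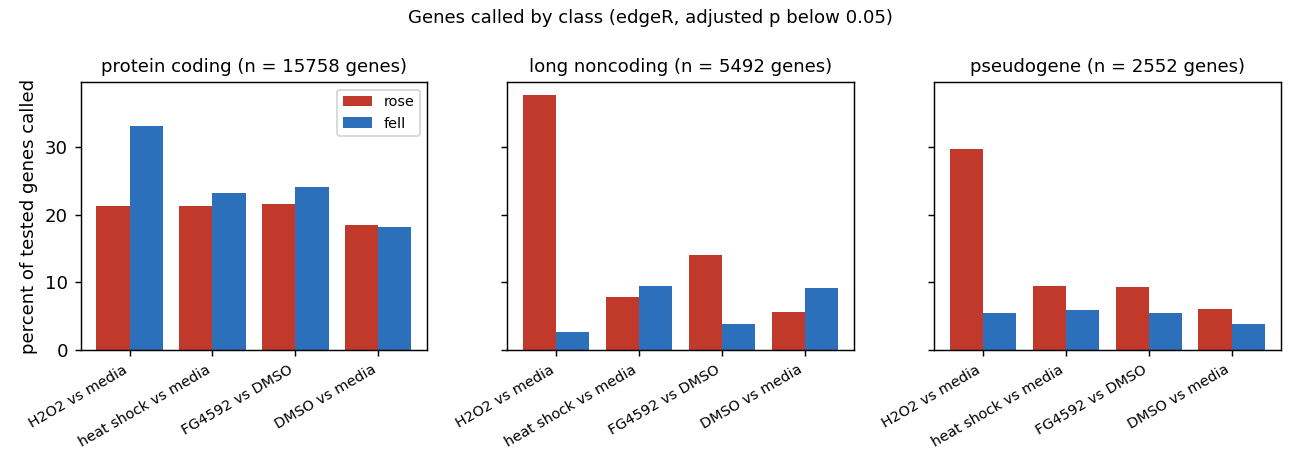
Percent of genes that rose or fell (y axis, percent of genes tested) in each comparison (x axis) at an adjusted p under 0.05. Protein-coding genes, long noncoding genes and pseudogenes have a panel each, and other classes are not shown. After H2O2, 37.6% of 5492 long noncoding genes rose and 2.73% fell, against 7.85% and 9.52% after heat shock. The same genes are the base of each share, and the filter that kept them can be met by H2O2 reads alone.

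By class, 3358 of 15758 protein-coding genes rose after H2O2 and 5206 fell, with a median of -0.099 log2. In a fit of these genes alone, chosen after the data were seen, 4425 rose and 3825 fell, with a median of 0.083. Which direction prevails among them therefore depends on the genes fitted. The median log2 fold change of long noncoding genes was 1.38, and 1.38 with 608 genes at 0 in a group set to their value against the floor. The filter ran over all 5 groups, so genes kept through their H2O2 reads alone were counted and could hardly fall. Fits of the compared groups alone tested 22989 genes of all classes for H2O2 and 19577 for heat shock. With a filter of 1 CPM in 3 libraries the long noncoding median was 1.14. These RNAs held 2.27% ± 0.0860 of counts in H2O2 and 0.953% ± 0.106 in media (SD, n = 3).

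Heat shock against media asks how a heat pulse changes the same fraction. The inducible chaperone gene HSPA6 rose 569-fold, and DNAJB1, a co-chaperone gene, 5.54-fold. Mitosis genes fell, and ribosomal protein and metallothionein genes rose in calls lost with an estimated correlation (adjusted p = 0.505 and adjusted p = 0.28). Of the genes that changed, 3987 also changed in the same direction in DMSO against media, chaperone and HIF target genes among them. YTHDF1 rose 2.02-fold, also when compared with DMSO (0.76 log2).

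Heat shock changed 8493 of 24739 genes, 4125 up and 4368 down, of which 1839 rose and 1458 fell at least 2-fold. With the DMSO libraries as controls 3601 of the 8493 (42.4%) kept their direction and call, 528 were called in the opposite direction and 4364 were not called. HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526894) rose from 0.311 ± 0.00408 CPM to 178 ± 20.1 CPM (SD, n = 3; log2 fold change 9.15, SE 0.36, adjusted p = 7.41e-10). Its neighbour HSPA7, a pseudogene of close sequence and so of uncertain value, rose 206-fold. The other largest rises were GPRACR, a long noncoding RNA (44.8-fold), RASSF10 of the RAS association family (33.5-fold) and BIVM-ERCC5. The last had no media count, was 1500-fold higher against the floor of 3 counts, and is uncertain, as above. BIVM-ERCC5 was not called without media replicate 1 (13.55), media replicate 2 (13.56) or media replicate 3 (13.56). The largest falls were the adenosine receptor ADORA2A (12.7-fold, overlapped by a readthrough gene), the ubiquitin ligase NEURL3 (10.5-fold), the adapter GRB7 (9.73-fold), the autophagy regulator DEPP1 (8.67-fold) and the mechanosensitive ANKRD1 (8.52-fold). Against DMSO, ADORA2A was not called and ANKRD1 was higher (1.68 log2).

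YTHDF1 measured 87.9 ± 8.05 CPM in media and 178 ± 7.61 CPM after heat shock (SD, n = 3; log2 fold change 1.02, SE 0.09, adjusted p = 8.14e-07). G3BP1 was not called (0.13 log2, adjusted p = 0.31). HSPA1A and HSPA1B rose 2.52-fold and 3.21-fold over media, and neither was called over DMSO (0.12 and 0.20 log2). HMOX1 rose 3.78-fold and CDKN1A 1.55-fold. AHNAK, DYNC1H1 and ACTB fell 1.6-fold, 1.74-fold and 1.68-fold, NORAD and TFRC rose 1.46-fold and 1.69-fold, and GAPDH and CA9 were not called (-0.09 and -0.42 log2). Against DMSO, AHNAK was higher, GAPDH lower (-0.70 log2), and DYNC1H1, ACTB, NORAD and TFRC were not called. CA9 was called without media replicate 1 (-0.59). NORAD was not called without heat shock replicate 1 (0.52), heat shock replicate 3 (0.53), media replicate 1 (0.44) or media replicate 2 (0.54), and ACTB was not called without heat shock replicate 1 (-0.71), heat shock replicate 3 (-0.72) or media replicate 2 (-0.57).

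Of the 26 lists, 8 were called after heat shock, a number that 3 of 10 splits, the real one included, reached (highest other 8). These splits have the same limit as those for H2O2. Only 1 of the 8 lists, mitosis, was also called with an estimated correlation. All but 1 of its 24 genes fell (0 and 23 adjusted over the list alone, median -1.51, adjusted p = 2.49e-29, and adjusted p = 0.0263 with an estimated correlation), led by the spindle gene ASPM (4.36-fold) and the checkpoint kinase BUB1 (4.33-fold). Of 78 ribosomal protein genes, 69 rose and 0 fell (75 and 0 adjusted over the list alone) (adjusted p = 1.55e-19, and adjusted p = 0.505 with an estimated correlation), RPS12 3.16-fold and RPS29 2.58-fold. RPS29 was not called without heat shock replicate 1 (1.01). All 8 metallothioneins rose (8 and 0 adjusted over the list alone; adjusted p = 4.62e-05, and adjusted p = 0.28 with an estimated correlation), MT1G 4.37-fold and MT1M 3.64-fold, though neither of the pair was called against DMSO. These 3 lists were also called, in the same direction, with DMSO as the control.

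The other 5 calls were not kept in that way with DMSO as the control. Heat shock chaperones were called up, since 15 rose and 3 fell (15 and 3 adjusted over the list alone) of 27 (adjusted p = 8.78e-05, and adjusted p = 0.505 with an estimated correlation), and HIF targets too, 11 rose and 2 fell (11 and 2 adjusted over the list alone) of 28 (adjusted p = 0.002, and adjusted p = 0.666 with an estimated correlation). In the second, VEGFA, an angiogenic factor, rose 5.19-fold, ANGPTL4 of lipid metabolism 4.77-fold and EGLN3 3.76-fold, the last 2 not called against DMSO. Inflammatory mediators were called down, 1 rose and 11 fell (1 and 11 adjusted over the list alone) of 21 (adjusted p = 0.00545, and adjusted p = 0.666 with an estimated correlation), TNF 3.03-fold and CSF2 3.02-fold, both of which were higher than in DMSO. Tubular injury markers were called down, 1 rose and 10 fell (1 and 11 adjusted over the list alone) of 20 (adjusted p = 0.00628, and adjusted p = 0.666 with an estimated correlation), with VCAM1 of cell adhesion down 2.29-fold and SOX9 up 2.31-fold. None of these 4 was called against DMSO. Glycolysis was called up, 9 rose and 5 fell (9 and 5 adjusted over the list alone) of 21 (adjusted p = 0.049, and adjusted p = 0.666 with an estimated correlation), PFKFB3 4.6-fold and ALDOC 5.43-fold, ALDOC not being called against DMSO. The list's call was at the threshold, held as an up call in 6 of 14 settings and was not called without heat shock replicate 1 at 0.0768, heat shock replicate 2 at 0.0647, heat shock replicate 3 at 0.0736, media replicate 1 at 0.175 or media replicate 3 at 0.0585. Its median was -0.0043, of opposite sign to its mean (0.42) and to its median under DESeq2 factors (0.0084). Against DMSO it was called down, with 12 falls and 3 rises.

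Lists not called after heat shock were ER chaperones (9 rose and 3 fell of 18, 10 and 4 adjusted over the list alone, adjusted p = 0.0919, called without media replicate 2 at 0.0233), with DNAJB9 up 3.14-fold and EDEM1 up 2.47-fold, and immediate early genes (13 rose and 7 fell of 29, 13 and 8 adjusted over the list alone, adjusted p = 0.0919, called without heat shock replicate 3 at 0.0119), with EGR3 up 27.7-fold and FOS up 20.4-fold. The ATF4 response (3 rose and 8 fell of 24, 4 and 9 adjusted over the list alone, adjusted p = 0.669) held a rise of the amino acid transporter SLC7A5 (5.71-fold) and a fall of CHAC1 (2.57-fold), which was higher than in DMSO. Of the NRF2 targets (7 rose and 8 fell of 25, 7 and 8 adjusted over the list alone, adjusted p = 0.687) SRXN1, a sulfiredoxin gene, rose 4.09-fold. The proapoptotic BBC3 fell 7.65-fold and the repair gene XPC 2.87-fold in the p53 list (7 rose and 10 fell of 25, 7 and 10 adjusted over the list alone, adjusted p = 0.253). In the BCL2 family (5 rose and 8 fell of 21, 5 and 8 adjusted over the list alone, adjusted p = 0.562) BCL2L11 rose 3.48-fold, not called against DMSO. Stress granule proteins were not called (4 rose and 8 fell of 30, 4 and 8 adjusted over the list alone, adjusted p = 0.669), with ATXN2 and UBAP2L down 2.52-fold and 2.33-fold, nor was the m6A list (5 rose and 10 fell of 20, 5 and 11 adjusted over the list alone, adjusted p = 0.123). In the latter the methyltransferase METTL3 fell 3.02-fold and the reader IGF2BP3 2.68-fold. DNA replication (3 rose and 10 fell of 26, 4 and 10 adjusted over the list alone, adjusted p = 0.562) held rises of the cyclins CCNE2 (4.08-fold) and CCNE1 (2.44-fold), neither called against DMSO.

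Sterol genes (5 rose and 7 fell of 22, 5 and 8 adjusted over the list alone, adjusted p = 0.375) split, with INSIG1 up 2.57-fold and FDFT1 down 2.34-fold, FDFT1 not being called against DMSO. Oxidative phosphorylation (10 rose and 9 fell of 34, 13 and 10 adjusted over the list alone, adjusted p = 0.692) included COX7C up 1.88-fold and SDHA down 1.74-fold. The list of known long noncoding RNAs (6 rose and 3 fell of 12, 6 and 3 adjusted over the list alone, adjusted p = 0.398) included SNHG5 and SNHG1 up 2.36-fold and 2.14-fold, of which SNHG5 was not called against DMSO. Of proximal tubule genes (2 rose and 3 fell of 14, 2 and 3 adjusted over the list alone, adjusted p = 0.669), CUBN and GGT1 fell 3.22-fold and 1.84-fold, and of fibroblast genes (2 rose and 1 fell of 14, 2 and 1 adjusted over the list alone, adjusted p = 0.931), COL6A1 rose 2.0-fold and LUM fell 1.34-fold. None of these 4 genes was called against DMSO. CUBN was not called without heat shock replicate 1 (-1.45) or media replicate 1 (-1.13). With edgeR 0 of 13 mitochondrial mRNAs were called (adjusted p = 0.931), nor were any by DESeq2, by limma-voom or at an unadjusted p under 0.05. MT-CO1 stood at -0.44 log2, and at 0.06 without media replicate 2. Of 11 endothelial genes edgeR called 0 (adjusted p = 0.978; 2 at an unadjusted p under 0.05) and DESeq2 and limma-voom 1 each, with EGFL7 at -0.35 log2. Leukocyte markers (1 rose and 1 fell of 9, 1 and 1 adjusted over the list alone, adjusted p = 0.781) held a fall of CD68 (5.35-fold), and histones (1 rose and 0 fell of 14, 1 and 0 adjusted over the list alone, adjusted p = 0.32) a rise of H2BC12 (1.69-fold), not called against DMSO. Median and mean differed in sign for NRF2 targets, p53 targets, proximal tubule, fibroblast, leukocyte and mitochondrial genes, all of them not called. Against DMSO 4 further lists were called: ATF4 targets and immediate early genes up, DNA replication and stress granule proteins down.

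**Figure D3:**
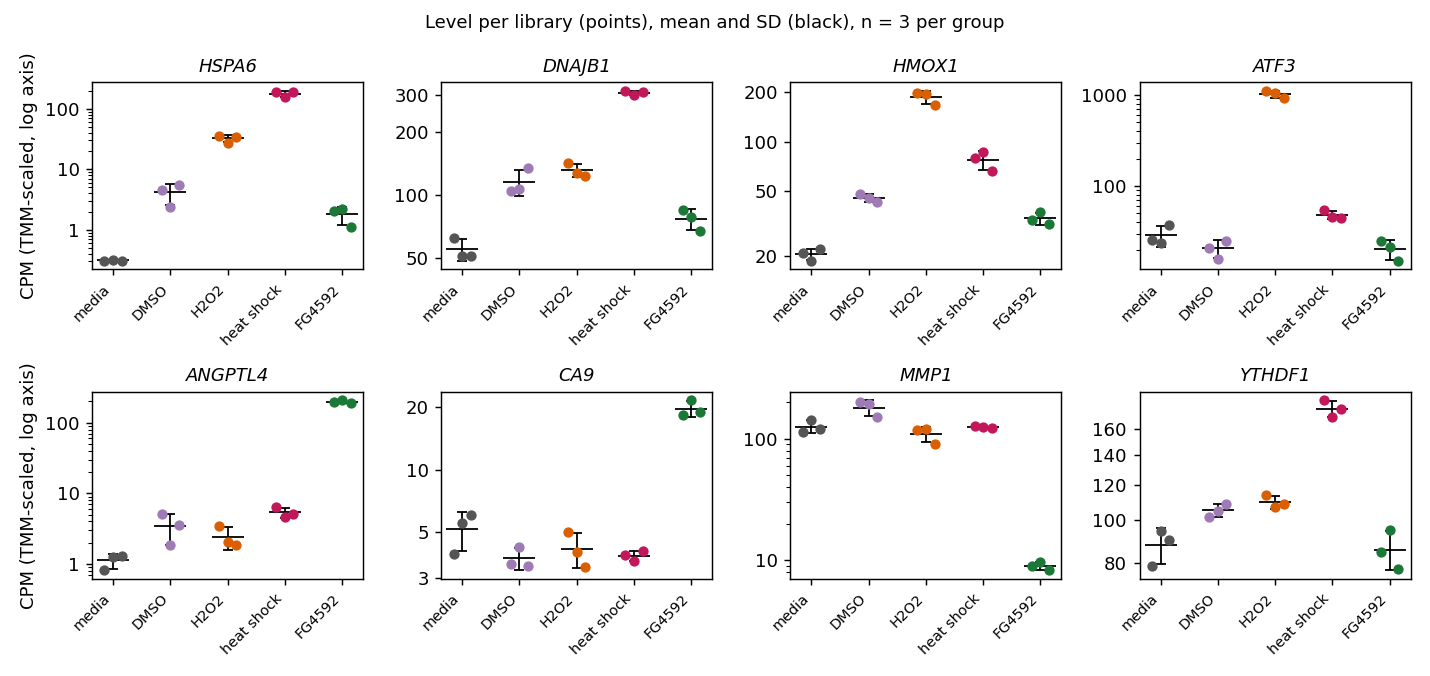
Level of 8 named genes (CPM, log axis) in each of the 15 libraries by group, with points for libraries and bars for the mean ± SD. HSPA6 lay at 178 CPM on average after heat shock against 0.311 in media, and ANGPTL4 at 198 CPM after FG4592 against 3.47 in DMSO.

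FG4592 against DMSO asks what HIF stabilisation changes in the fraction, relative to its vehicle. ANGPTL4, a HIF target of lipid metabolism, rose 57.1-fold, and CA9, a carbonic anhydrase gene under HIF control, 5.23-fold. HIF targets, glycolysis and cholesterol synthesis rose as lists and inflammatory mediators such as IL6 fell, all calls lost with an estimated correlation (adjusted p = 0.288, adjusted p = 0.4, adjusted p = 0.0552 and adjusted p = 0.119). The collagenases MMP1 and MMP13 and the matrix gene FN1 fell as well. YTHDF1 fell 1.23-fold, a call lost in 3 of 12 alternatives.

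FG4592 changed 8659 of 24739 genes, with 4486 rises and 4173 falls, at least 2-fold in 2072 and 1516. A fit of these groups alone called 7340 genes, and 4542 with a replicate block. ANGPTL4 (ENSG00000167772, chromosome 19, 8363289 to 8374370) went from 3.47 ± 1.59 CPM to 198 ± 8.31 CPM (SD, n = 3; log2 fold change 5.84, SE 0.32, adjusted p = 7.44e-09). CA9 (ENSG00000107159, chromosome 9, 35673918 to 35681159) went from 3.74 ± 0.456 CPM to 19.6 ± 1.68 CPM (SD, n = 3; log2 fold change 2.39, SE 0.20, adjusted p = 2.85e-07). MMP1 (ENSG00000196611, chromosome 11, 102789919 to 102798160) went from 181 ± 26.9 CPM to 8.93 ± 0.683 CPM (SD, n = 3; log2 fold change -4.34, SE 0.15, adjusted p = 1.74e-10). The other large rises were C4orf47 (11.6-fold), the pseudogene HLA-V (11.6-fold, of a family with shared reads), the long noncoding OLMALINC (11.1-fold) and RAB43. The other large falls were MMP13 (22.1-fold), the tight junction gene CLDN2 (19.2-fold), the growth factor EREG (16.4-fold) and ISY1-RAB43. RAB43 was 15.9-fold higher. The readthrough gene ISY1-RAB43, with no FG4592 count, was 1880-fold lower with FG4592 set to the floor of 3 counts. These models share exons, so both values are uncertain.

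YTHDF1 measured 105 ± 3.59 CPM in DMSO and 85.9 ± 8.67 CPM after FG4592 (SD, n = 3; log2 fold change -0.29, SE 0.09, adjusted p = 0.0199). Its adjusted p ran from 0.00359 to 0.157 over 12 alternatives. It was not called with replicate number as a block, without DMSO replicate 3 (adjusted p = 0.0635) or without FG4592 replicate 3 (adjusted p = 0.0813). G3BP1 fell 1.98-fold (adjusted p = 1.2e-06). GAPDH rose 2.1-fold, CDKN1A 1.33-fold and VEGFA 1.35-fold. CDKN1A was not called without FG4592 replicate 2 (0.34), and VEGFA was not called without DMSO replicate 2 (0.30), DMSO replicate 3 (0.44), FG4592 replicate 2 (0.36) or FG4592 replicate 3 (0.37). HSPA1A, HSPA1B, DNAJB1 and HMOX1 fell 1.8-fold, 2.23-fold, 1.5-fold and 1.33-fold. DNAJB1 and HMOX1 were not called in every alternative, their highest adjusted p over 12 being 0.0514 and 0.0811. EGLN3, itself a HIF target, was not called (-0.10 log2, adjusted p = 0.643), and neither were AHNAK (0.02), DYNC1H1 (0.23), NORAD (0.07), TFRC (-0.33) and ACTB (-0.57, adjusted p = 0.0724). ACTB was called without DMSO replicate 3 (-0.75) or FG4592 replicate 3 (-0.90), DYNC1H1 was called without DMSO replicate 1 (0.30), and TFRC was called without FG4592 replicate 1 (-0.66).

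Camera called 14 lists after FG4592, none of them with an estimated correlation. The highest other of 10 splits of these libraries called 13, with the same limit as the splits for H2O2. HIF targets other than glycolysis were up, 15 rose and 4 fell (17 and 4 adjusted over the list alone) of 28 (adjusted p = 8.47e-06, and adjusted p = 0.288 with an estimated correlation), with the lipid droplet gene HILPDA up 6.63-fold. Cholesterol synthesis was up, 15 rose and 0 fell (16 and 0 adjusted over the list alone) of 22 (adjusted p = 5.98e-09, and adjusted p = 0.0552 with an estimated correlation), FDFT1 3.27-fold and MVK 3.1-fold. Glycolysis was up, 12 rose and 4 fell (12 and 4 adjusted over the list alone) of 21 (adjusted p = 0.0423, and adjusted p = 0.4 with an estimated correlation), a call held in 7 of 13 settings and not called without DMSO replicate 2 at 0.0683, DMSO replicate 3 at 0.0527 or FG4592 replicate 1 at 0.0726, with the enolase ENO2 up 4.77-fold and PFKFB3 down 2.94-fold. Nuclear oxidative phosphorylation was up, 18 rose and 1 fell (20 and 1 adjusted over the list alone) of 34 (adjusted p = 0.000626, and adjusted p = 0.471 with an estimated correlation), COX6C 2.16-fold and UQCRQ 1.99-fold. UQCRQ was not called in every alternative, its highest adjusted p over 12 being 0.0873. Mitosis was up, 8 rose and 0 fell (8 and 0 adjusted over the list alone) of 24 (adjusted p = 0.00185, and adjusted p = 0.404 with an estimated correlation), BUB1 2.07-fold and the kinase AURKB 1.94-fold, but not called with a replicate block (adjusted p = 0.0549).

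Inflammatory mediators were called down after FG4592, 1 rose and 16 fell (1 and 16 adjusted over the list alone) of 21 with a median of -1.30 (adjusted p = 2.04e-09, and adjusted p = 0.119 with an estimated correlation). IL6, a cytokine, fell 7.74-fold and CXCL3, a chemokine, 8.73-fold. Tubular injury markers were down, 2 rose and 12 fell (3 and 13 adjusted over the list alone) of 20 (adjusted p = 4.82e-06, and adjusted p = 0.167 with an estimated correlation), VCAM1 11.7-fold and SOX9 6.3-fold. Fibroblast and matrix genes were down, 0 rose and 9 fell (0 and 9 adjusted over the list alone) of 14 (adjusted p = 4.33e-06, and adjusted p = 0.0552 with an estimated correlation). FN1, a fibronectin gene, fell 4.7-fold from 22208 ± 3149.5 CPM (SD, n = 3), and POSTN 7.01-fold. Proximal tubule transport was down, 0 rose and 4 fell (0 and 4 adjusted over the list alone) of 14 (adjusted p = 0.00359, and adjusted p = 0.0552 with an estimated correlation), with the bicarbonate transporter SLC4A4 5.44-fold and the peptidase ANPEP 3.34-fold lower.

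Stress granule protein genes were down as well, 2 rose and 20 fell (3 and 20 adjusted over the list alone) of 30 (adjusted p = 7.86e-07, and adjusted p = 0.0552 with an estimated correlation), SND1 2.55-fold and the helicase DDX3X 2.24-fold. The m6A list was down, 3 rose and 9 fell (3 and 10 adjusted over the list alone) of 20 (adjusted p = 0.0453, and adjusted p = 0.4 with an estimated correlation), called in 6 of 13 settings and not called without DMSO replicate 2 at 0.076, FG4592 replicate 1 at 0.0603 or FG4592 replicate 2 at 0.0516, FTO 2.01-fold and the indirect reader HNRNPC 1.78-fold. ER chaperones were down, 1 rose and 10 fell (1 and 10 adjusted over the list alone) of 18 (adjusted p = 0.000115, and adjusted p = 0.314 with an estimated correlation), HSPA5 2.28-fold and HYOU1 1.98-fold. Metallothioneins were down, 0 rose and 5 fell (0 and 5 adjusted over the list alone) of 8 (adjusted p = 0.00857, and adjusted p = 0.32 with an estimated correlation), MT1G 2.18-fold and MT1X 2.05-fold. Mitochondrial mRNAs were down, 0 rose and 4 fell (0 and 4 adjusted over the list alone) of 13 (adjusted p = 0.0237, and adjusted p = 0.637 with an estimated correlation), called in 8 of 13 settings and not called without DMSO replicate 2 at 0.089, FG4592 replicate 1 at 0.0721 or FG4592 replicate 2 at 0.0713. MT-ND4L fell 2.82-fold and MT-ATP8 2.82-fold, each overlapping a neighbouring mitochondrial gene. Mitochondrial genes, rRNA included, held 0.793%, 0.742% and 1.98% of counts in FG4592 replicates 1 to 3 and 1.43%, 2.05% and 0.842% in those of DMSO, so the groups overlap and FG4592 replicate 3 stands apart from its group. MT-ND4L was not called without DMSO replicate 1 (-1.52), DMSO replicate 2 (-1.01), FG4592 replicate 1 (-1.24) or FG4592 replicate 2 (-1.17), MT-ATP8 was not called without DMSO replicate 2 (-1.12), FG4592 replicate 1 (-1.37) or FG4592 replicate 2 (-1.17), and MT1G was not called without DMSO replicate 3 (-0.82).

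The remaining 12 lists were not called after FG4592. In heat shock chaperones (6 rose and 10 fell of 27, 6 and 11 adjusted over the list alone, adjusted p = 0.0723, called without DMSO replicate 3 at 0.0481 or FG4592 replicate 3 at 0.0328) HSPA8 fell 4.12-fold and DNAJB2 rose 2.93-fold. In NRF2 targets (8 rose and 1 fell of 25, 8 and 1 adjusted over the list alone, adjusted p = 0.0512, called without DMSO replicate 2 at 0.0431 or FG4592 replicate 3 at 0.0344) PIR rose 3.5-fold and OSGIN1 2.29-fold, and in p53 targets (8 rose and 8 fell of 25, 9 and 9 adjusted over the list alone, adjusted p = 0.598) AEN and PLK2 fell 2.91-fold and 2.74-fold. In the ATF4 response (8 rose and 7 fell of 24, 8 and 8 adjusted over the list alone, adjusted p = 0.606) SLC7A5 fell 3.4-fold and TRIB3 rose 2.64-fold. In immediate early genes (8 rose and 7 fell of 29, 8 and 7 adjusted over the list alone, adjusted p = 0.89, median -0.01, mean 0.02) EGR1 rose 6.68-fold and FOS 5.18-fold. The BCL2 family (3 rose and 9 fell of 21, 3 and 9 adjusted over the list alone, adjusted p = 0.283) held a rise of BAD (2.28-fold) and a fall of BBC3 (1.73-fold). DNA replication (7 rose and 10 fell of 26, 7 and 12 adjusted over the list alone, adjusted p = 0.206) held falls of CCNE2 (2.84-fold) and MCM6 (2.04-fold), and ribosomal proteins (3 rose and 15 fell of 78, 3 and 12 adjusted over the list alone, adjusted p = 0.0752, called without DMSO replicate 2 at 0.000819, FG4592 replicate 1 at 0.0176 or FG4592 replicate 2 at 0.0485) falls of RPL3 (1.76-fold) and RPL10A (1.64-fold). CRNDE rose 2.42-fold and GAS5 fell 1.63-fold in the list of known long noncoding RNAs (3 rose and 1 fell of 12, 3 and 1 adjusted over the list alone, adjusted p = 0.336). Histones (0 rose and 3 fell of 14, 0 and 3 adjusted over the list alone, adjusted p = 0.589, mean 0.02 and median -0.04) held falls of H2BC21 (2.7-fold) and H2AC6 (2.22-fold). In leukocyte genes (0 rose and 3 fell of 9, 0 and 0 adjusted over the list alone, adjusted p = 0.36) CD68 fell 2.36-fold and ITGAM 2.19-fold. For endothelial genes (0 rose and 2 fell of 11, 0 and 2 adjusted over the list alone, adjusted p = 0.49) EGFL7 was 0.29 log2. BBC3 was not called without DMSO replicate 1 (-0.76) or FG4592 replicate 3 (-0.59), CD68 was not called without DMSO replicate 1 (-1.30), DMSO replicate 2 (-0.77), FG4592 replicate 1 (-0.93) or FG4592 replicate 2 (-1.06), ITGAM was not called without DMSO replicate 1 (-1.06), DMSO replicate 2 (-1.20), DMSO replicate 3 (-1.13), FG4592 replicate 1 (-0.78) or FG4592 replicate 2 (-1.25), H2AC6 was not called without DMSO replicate 3 (-0.82), and EGFL7 was called without DMSO replicate 1 (0.46).

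**Figure D4:**
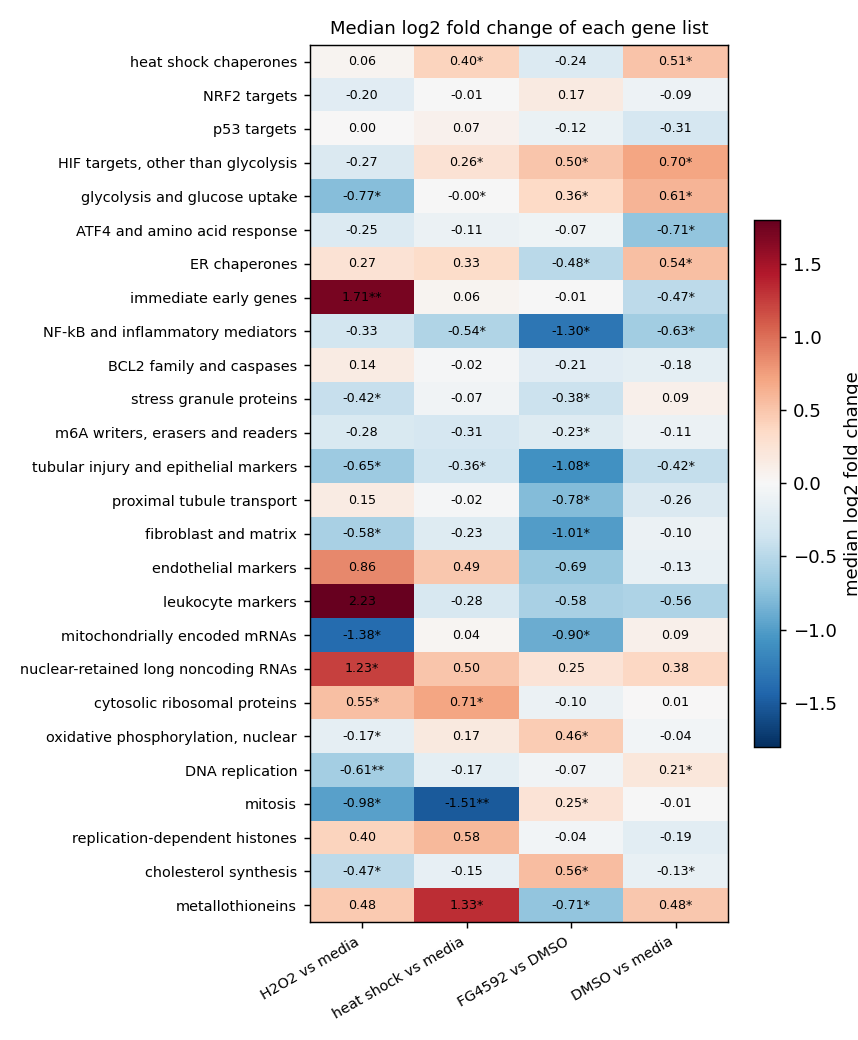
Median log2 fold change (colour) of the 26 gene lists (y axis) in 4 comparisons (x axis), with 1 asterisk for a camera adjusted p under 0.05 at the preset correlation and 2 for one also under 0.05 with an estimated correlation. Immediate early genes stood at 1.71 after H2O2 and mitosis at -1.51 after heat shock; of the lists called, glycolysis after heat shock (-0.0043) and oxidative phosphorylation after H2O2 (-0.17) change sign under another scaling.

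DMSO against media compares the 2 control groups, which differ in vehicle. DMSO was given for 12 h, while for media the labels state no time, and for neither a culture batch. ANKRD1 fell 27.3-fold, and the microRNA host gene MIR205HG 19.4-fold. HSPA6 and HSPA8 (chosen after their values were seen) rose 13.3-fold and 3.6-fold, while the small heat shock protein genes CRYAB and HSPB1 (likewise) fell 2.39-fold and 1.73-fold. In all 6933 genes differed, 3457 up and 3476 down. KLHL14 rose 15.8-fold, and ZBED6, which lies within ZC3H11A and shares its reads, 15.6-fold. ISY1-RAB43, absent from media, was 1770-fold higher against the floor of 3 counts and RAB43 21.8-fold lower, both uncertain. ISY1-RAB43 was not called without media replicate 1 (13.80), media replicate 2 (13.81) or media replicate 3 (13.80). Tests of the lists in this comparison were added after the data were seen, and 11 were called, none with an estimated correlation. Chaperones were called up, 15 rose and 3 fell (19 and 3 adjusted over the list alone) of 27 (adjusted p = 2.07e-07, and adjusted p = 0.231 with an estimated correlation). HIF targets were too, 15 rose and 3 fell (16 and 4 adjusted over the list alone) of 28 (adjusted p = 6.3e-06, and adjusted p = 0.336 with an estimated correlation), as was glycolysis, where 14 rose and 0 fell (15 and 1 adjusted over the list alone) of 21 (adjusted p = 4.99e-09, and adjusted p = 0.0791 with an estimated correlation).

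ER chaperones were also above media in DMSO (11 rose and 1 fell of 18, 11 and 1 adjusted over the list alone, adjusted p = 0.000728), as were DNA replication (10 rose and 1 fell of 26, 10 and 1 adjusted over the list alone, adjusted p = 0.000243) and metallothioneins (3 rose and 0 fell of 8, 4 and 0 adjusted over the list alone, adjusted p = 0.0322). Below media were the ATF4 response (2 rose and 16 fell of 24, 2 and 17 adjusted over the list alone, adjusted p = 9.99e-07), immediate early genes (2 rose and 15 fell of 29, 4 and 17 adjusted over the list alone, adjusted p = 0.000569), inflammatory mediators (1 rose and 9 fell of 21, 1 and 10 adjusted over the list alone, adjusted p = 0.00168), tubular injury markers (1 rose and 8 fell of 20, 1 and 9 adjusted over the list alone, adjusted p = 6.62e-05) and cholesterol synthesis (1 rose and 7 fell of 22, 1 and 8 adjusted over the list alone, adjusted p = 0.0337). Estimated correlations gave adjusted p values of 0.231 for DNA replication, 0.336 for the ATF4 response and tubular injury, and 0.395 for the other 5.

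H2O2 against heat shock compares the 2 stressors that share their media controls. TAC3, a neuropeptide gene with no count in heat shock libraries, was 900-fold higher after H2O2 against the floor of 3 counts, and PTGER3 208-fold higher. The tubulin pseudogene TUBB8P7, from a family with shared reads, was 232-fold higher. GPR183, an oxysterol receptor gene, was 32.2-fold lower, GPRACR 23.5-fold and the homeobox gene HOXA7 16.6-fold lower. In total 11161 genes differed, 6010 higher and 5151 lower after H2O2. Upper-quartile factors raised the median of all genes by 0.23 log2 and gave 7700 and 3129 (71.1% higher, against 53.8%).

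Both stressors changed 4605 genes in the same direction relative to media, 2045 up and 2560 down, and 905 in opposite directions. DMSO shared 2639 genes with H2O2 in the same direction relative to the same media libraries and 1373 in opposite ones. Independent lists of the same sizes as those of the stressors would share 1081 rises and 981 falls. The log2 fold changes of 11943 genes of at least 5 CPM had a correlation of 0.50 across genes, and 20 simulations of unchanged groups with shared controls gave a mean of 0.50. Their covariance was 0.297, against a simulated mean of 0.0242. Genes are not independent replicates, and 3 media libraries cannot be divided to give each comparison its own controls.

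Whether responses to FG4592 and to a stressor differ was tested as a difference of differences, each against its own controls. Against the H2O2 response 9182 genes differed, 4682 with a higher and 4500 with a lower FG4592 response. Upper-quartile factors moved the median of all genes by -0.20 log2 and gave 3448 and 5481 (38.6% higher, against 51.0%), and DESeq2 factors moved it by -0.12. Of these genes 1776 were called in opposite directions in the 2 comparisons and 871 in the same. Against the heat shock response 9634 genes differed, 4973 higher and 4661 lower, with 2938 called in opposite directions and 349 in the same. HSPA6 differed by -7.91 and -10.35 log2, ANGPTL4 by 4.71 and 3.58, CA9 by 2.71 and 2.81, GAPDH by 2.11 and 1.16, and YTHDF1 by -0.61 and -1.31. G3BP1 differed from the heat shock response (-1.12) but not from that to H2O2 (0.06, adjusted p = 0.771). The 2 control groups differ in vehicle, and the labels do not say whether in time or culture batch, so these contrasts carry any such difference.

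Transcript length was compared with log2 fold change across 15729 protein-coding genes, because granule mRNAs are known to be long. After FG4592 Spearman's rho across genes was -0.240, and the median fell from 0.43 log2 for transcripts up to 1 kb to -0.29 above 8 kb. Of 10 splits of these libraries, 2 gave a rho of at least this size, the highest other being 0.241. DYNC1H1 and AHNAK, long transcripts fixed in advance, were not called in that comparison. For H2O2 rho was -0.0932 and for heat shock -0.0259. The value for H2O2 was -0.0028 among genes of at least 10 CPM.

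**Figure D5:**
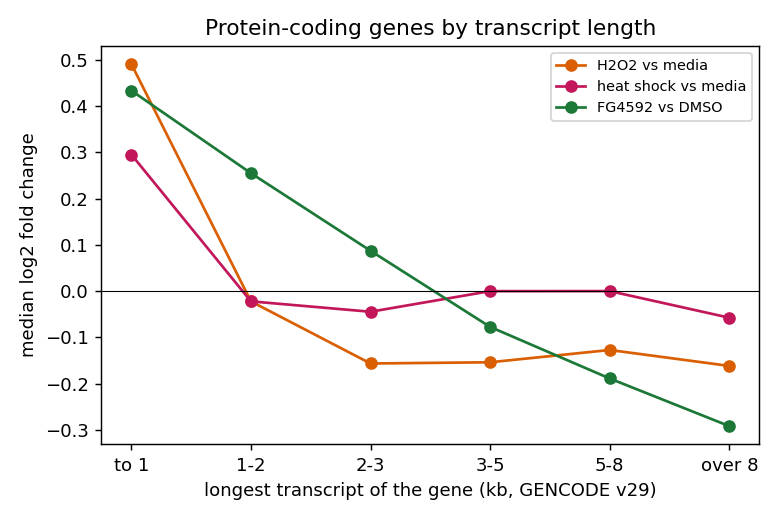
Median log2 fold change (y axis) of protein-coding genes binned by transcript length (x axis, kb) in 3 comparisons. After FG4592 the median goes from 0.43 in transcripts up to 1000 bases to -0.29 in those above 8000, a trend whose size (rho) another split of the same libraries also reached.

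The authors' own tables, with a 2-fold minimum, marked 7607 genes for H2O2 (7116 up, 491 down), 3036 for heat shock (1867 up, 1169 down) and 3567 for FG4592 (2558 up, 1009 down). Of these, 5790, 2826 and 3306 were also called by edgeR here, each in the same direction. The authors' H2O2 genes were 93.6% up, against 4881 rises and 1303 falls of at least 2-fold by edgeR with TMM.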

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

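No test in this part was chosen after its result was seen, but genes named here outside the rule for named genes were. Each result here was raised by the test of the difference between responses, in which the FG4592 response (against DMSO) is set against the response to another stressor (against media).

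In 9182 of 24739 genes the FG4592 response differed from the H2O2 response. Of these 1776 were called in opposite directions by the 2 comparisons, 871 in the same direction by unequal amounts, 2418 only after FG4592, 3801 only after H2O2 and 316 in neither. ATF3 (5.15 log2 after H2O2) differed by -5.16 and FOS by -3.81, both with the higher response to H2O2, while ANGPTL4 differed by 4.71 the other way. The mitotic kinase gene BUB1, which rose after FG4592, differed by 2.23. Of 100 drawn splits of the libraries, only the real one gave a count as large, and the highest of the others was 2081. The splits mix the libraries of all groups compared, so they show that the groups differ. They cannot test whether the 2 responses are equal, nor exclude chance between cultures if the replicates are technical.

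The FG4592 response differed from the heat shock response in 9634 genes. Opposite calls numbered 2938, same-direction calls 349, calls only after FG4592 2901, calls only after heat shock 2797 and calls in neither 649. HSPA6 differed by -10.35 log2, VEGFA by -1.94 and G3BP1 by -1.12, all with the lower response to FG4592 (VEGFA rose in both), and BUB1, which fell after heat shock, by 3.16. Here too, of 100 drawn splits, only the real one gave a count as large, and the highest other was 4857, with the same limits. The 2 responses were measured against different controls. Because 6933 genes differed between those controls (1 of 10 splits gave as many, the highest other being 0, and 10 splits are too few for a share under 0.05), what the treatments and the controls each contribute stays untested.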

How the results depend on the processing

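Chosen after the data were seen were the DMSO libraries as controls, counts divided by 4, protein-coding genes alone and list medians under other scalings; the other alternatives were planned. All stayed within 1.5 times the reported count for the 5 comparisons of a pair of groups and both differences of responses, with 1 exception. Lowest and highest counts were 8250 and 13515 for H2O2, 6653 and 9200 for heat shock, 5458 and 7831 for DMSO against media, 7546 and 13544 for H2O2 against heat shock, and 7359 to 10946 and 8091 to 10223 for FG4592 against the H2O2 and heat shock responses. Like counts need not hold the same genes. With DMSO controls, 48.6% of the heat shock calls and 75.1% of the H2O2 calls were called again, in either direction. The lowest counts for H2O2 and for H2O2 against heat shock came from 15758 protein-coding genes alone. The overlap of H2O2 and heat shock ran from 4051 to 4923. The exception was FG4592, at 4542 with a replicate block in a fit of its groups alone, against 7340 in that fit without the block; the cause was not tested. The other FG4592 counts reached 9364. For DMSO against media the block went the other way, from 5458 calls without it to 6508. Leaving out 1 library gave 10295 to 11434, 6970 to 7536, 6982 to 8116, 5861 to 6195 and 9279 to 9805 in the order H2O2, heat shock, FG4592, DMSO, H2O2 against heat shock. For the differences of responses it gave 7963 to 9018 and 8666 to 9418.

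With an estimated correlation, which widens the test, 2 lists were called for H2O2, 1 for heat shock and 0 for FG4592, against 12, 8 and 14. Leaving out 1 library gave 12 to 14, 7 to 9 and 12 to 16. Among lists called, the medians of 2 changed sign with scaling: glycolysis after heat shock to 0.0084 with DESeq2 factors, and oxidative phosphorylation after H2O2 to 0.021 with upper-quartile factors. With a filter of 1 CPM, stress granule proteins, cholesterol synthesis and oxidative phosphorylation were no longer called after H2O2 (adjusted p = 0.0518, 0.0771 and 0.108), nor m6A and mitochondrial mRNAs after FG4592 (0.132 and 0.112), while ER chaperones after H2O2 (0.0495) and immediate early genes after heat shock (0.0471) were. Without a filter, calls were gained by NRF2 targets and m6A after H2O2 (0.00961 and 0.00156), m6A after heat shock (0.0366), and NRF2 targets, chaperones and ribosomal proteins after FG4592 (0.0392, 0.016 and 0.0032), and lost by glycolysis after heat shock (0.129). The block ended calls of oxidative phosphorylation after H2O2 (0.0552) and of mitosis, glycolysis and m6A after FG4592 (0.0549, 0.131 and 0.131), the last 2 also lost without the block in a fit of those groups alone (0.0972 and 0.102), and added m6A after H2O2 (0.0427).

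The length correlation after H2O2 went from -0.0932 to -0.040 with a filter of 1 CPM and to -0.0028 among genes of at least 10 CPM. After heat shock it was -0.0092 with the 1 CPM filter, and after FG4592 -0.271 for genes of at least 10 CPM. Each of these settings drops low genes.

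Named genes gave 2710 values under other settings, with 2612 of the same direction and side of the threshold, 65 no longer called, 22 newly called and 11 of opposite sign; DMSO controls are counted apart. Of the 11, MT-CO1 after heat shock ran from -0.66 to 0.064 when 1 library was left out (0.064 without media replicate 2), and EGLN3 after FG4592 from -0.19 to 0.011 (without FG4592 replicate 3). AHNAK after FG4592 was -0.0053 with DESeq2 factors, -0.014 without a filter, -0.038 with the block, and -0.039 to 0.090 with 1 library left out. NORAD was -0.013 with the block and -0.093 to 0.28 with 1 left out. None of these was called, and the cause was not tested.

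With DMSO as controls 87 of 138 values were the same, 27 no longer called, 2 newly called and 22 reversed, 6933 genes being called between DMSO and media. For H2O2 the reversed log2 values were EGLN3 -0.23, MT1G -0.96, HSPA1A -1.08, HSPA1B -1.13, CA9 0.15, VEGFA -0.96, AHNAK 0.98 and TFRC -0.60. For heat shock they were ADORA2A 0.44, ANKRD1 1.68, CHAC1 0.66, TNF 1.28, CSF2 0.70, COL6A1 -0.089, EGFL7 0.11, CCNE2 -0.062, G3BP1 -0.047, CA9 0.047, EGLN3 -0.34, AHNAK 0.85, TFRC -0.17 and ACTB 0.010. Simulated 4-fold changes were called for 89.4% of genes and 1.5-fold changes for 17.9%. These shares hold for the simulation, in which few genes changed, and not for the real comparisons. Depth was not varied, so whether it or the spread sets these shares was not tested.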

Other observations

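The tests of poly(A) selection, of mitochondrial RNA of every kind and of a heat-like stress were chosen, or their bounds rewritten, after the results were seen, as were the genes named in this part outside the rule; the others were set before. Poly(A) selection was first 1 test over both stressors that its low heat shock median would have excluded for both; it was then split by stressor, and nuclear rRNA genes were added. A heat-like stress was first to be excluded on HSPA6 alone, which would have excluded it; the chaperone median was added later.

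DMSO shares genes with heat shock beyond chaperones. VGF, a secreted neuropeptide precursor gene, rose 13.8-fold in DMSO and 13.8-fold after heat shock. RGS2, a regulator of G protein signalling, rose 6.95-fold and 21.9-fold, RSPO3, a WNT agonist, 9.4-fold and 20.9-fold, and ID3, an inhibitor of differentiation, 8.74-fold and 9.21-fold. Against media 3987 genes changed in the same direction in both and 255 in opposite ones. HSPA8 rose 1.78-fold after heat shock and 3.6-fold in DMSO, whereas CRYAB and HSPB1 fell in DMSO and were not called after heat shock. FG4592 was lower than DMSO in RGS2 (3.11-fold), RSPO3 (14.3-fold) and HSPA6 (2.3-fold).

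The DMSO and heat shock libraries thus lay on a like side of media. Their log2 fold changes had a covariance of 0.322, against at most 0.0320 in 20 simulated sets of unchanged groups sharing media. Their correlation was 0.630, against at most 0.601 in those sets. The simulated sets hold only the fitted spread within groups. The covariance argues against that spread as the cause, but not against a deviation of the media libraries as a whole. Whether the media libraries stand apart from all others stays open: over the 3987 genes the lower of the medians of H2O2 and FG4592 in the shared direction was 0.42 (0.39 to 0.45), but the genes were chosen for differing from the same media libraries and FG4592 includes the DMSO vehicle, so this value decides nothing. A heat-like stress in DMSO cultures also stays open, because HSPA6 reached 0.41 (0.33 to 0.48) of its heat shock log2 change while the chaperone medians had a ratio of 1.28. Vehicle, time in culture and culture batch, which the labels do not separate, were not tested.

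Mitochondrial rRNA was higher after both stressors. MT-RNR1 rose 14.5-fold after H2O2 and 22.2-fold after heat shock, and MT-RNR2 4.67-fold and 7.0-fold. More mitochondrial RNA of every kind is argued against by the mitochondrial mRNAs, whose median was -1.38 (-1.86 to -1.14) after H2O2 and 0.04 after heat shock. Weaker poly(A) selection may contribute in H2O2 libraries, where 56 RNAs without a tail had a median of 2.47 (0.64 to 3.28). Of the 56, 26 rose, 1 fell and 29 were not called. The 14 replication-dependent histones among them had a median of 0.40 and edgeR called 0 of them. The rises thus lie in the other members, and the histones go against weaker selection. In heat shock libraries the median of the 56 RNAs was 0.30 (0.01 to 0.61), with 50 of 56 not called, which goes against it. For 10 nuclear rRNA genes the median after heat shock was 0.81 (-0.40 to 3.91), and 4 rose and 6 were not called. After H2O2 the rRNA median was 1.93 (-0.22 to 3.74). These intervals run over gene models, not libraries, and are too wide to exclude weaker selection. Selection and a change in rRNA therefore cannot be told apart in either group.

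More genes were detected after H2O2, 32633 ± 337 against 24794 ± 681 in media (SD, n = 3), and long noncoding RNAs held 2.27% of counts against 0.953%. Among tested genes under 0.5 CPM in media, an expressed gene ending within 10 kb upstream on the same strand was beside 419 of 3233 that rose and 501 of 4380 others (odds ratio 1.15, 1.00 to 1.33, against 1.10, 0.93 to 1.304, for a gene starting downstream). The ratio for the upstream gene lies far below the 2 set in advance. Both sets hold only tested genes, however, and reads in H2O2 libraries alone can bring a near-silent gene past the filter. This may pull the ratio towards 1. It therefore does not decide on transcription that runs on over that distance, and longer run-on was not tested. Genomic DNA would raise distant and near genes alike, but the gain per kb over 100 kb from an expressed gene was 0.256 (0.219 to 0.303) of that within 10 kb, and the lowest median of long noncoding genes under 4 scalings was 1.38, so DNA and scaling as whole causes are argued against. Transcription running on, weaker poly(A) selection and a change in the RNA of stressed cells or of the fraction remain open.

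Libraries were also reassigned to the compared groups. With 6 libraries there are 10 splits, too few for a share under 0.05. The counts of changed genes were 12038 for H2O2 (highest other split 1), 8493 for heat shock (1), 8659 for FG4592 (2) and 11161 for H2O2 against heat shock (1), so 1 split of 10 gave as many in each. Lists called numbered 12 for H2O2 (highest other 13, with 6 splits at 12 or more), 8 for heat shock (highest other 8, with 3 splits) and 14 for FG4592 (highest other 13, with 1 split). For H2O2 and heat shock, other splits thus called as many lists as the real one. The size of the length correlation was 0.0932 after H2O2 (highest other 0.168, 4 splits), 0.0259 after heat shock (0.0918, 10 splits) and 0.240 after FG4592 (0.241, 2 splits). The overlap of 4605 genes was reached only by the real one of 100 drawn splits of 9 libraries (highest other 2611). These splits mix media with both stressors, so they show that the groups differ. They cannot separate the overlap from the effect of shared media libraries.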
